A study of Mus musculus with 4 samples.

How the data were processed

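Ribosome footprints were measured in 4 libraries of wild-type C57BL/6 mouse embryonic fibroblasts, 2 without and 2 with the PI3K inhibitor wortmannin. Per the labels' protocols, confluent cells were synchronised with dexamethasone, a glucocorticoid that sets circadian rhythms of cultured cells to a common phase. They were moved from 35 °C to 38.5 °C 24 h later. Lysis was in cycloheximide, which holds ribosomes on mRNA, and footprints were cut with RNase I, pelleted with ribosomes and depleted of rRNA before library preparation. The series text mentions independent experiments, and the labels do not say which libraries shared one. The p-values of single transcripts thus measure the spread between these libraries. Matched mRNA libraries were not analysed here, so a change in footprints was not separated into mRNA level and translation. No spike-in was used here, and all values are relative to the library.

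The deposited files give, for each of 63759 UCSC transcripts, a coding length in codons and a whole-number count of footprints, which the authors did not normalise as far as the values show. CASAVA 1.8, STAR 2.7.0 and the build mm10 are named per the submitters' processing notes; the counting tool is not given in the sources used here. Footprints shared by isoforms were counted in each isoform, so totals exceed the number of footprints. The length was not given for 17340 transcripts. Library totals were 15376778 and 31110420 in control replicates 1 and 2, and 7677780 and 7485868 in wortmannin replicates 1 and 2. The control libraries were thus the deeper ones.

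Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the default expression filter (a minimum count of 10), the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The standard error was the size of the log2 fold change divided by the square root of F. CPM values are counts scaled to library size and TMM factor. Counts were also simulated with few changes and the same spread in both groups, and 26232 transcripts were tested. The test called 15.2% of 66 changes of 1.5-fold, 62.1% of 66 of 2-fold and 95.3% of 64 of 4-fold, and 8.2% of its calls were false. In the real data 33.1% of transcripts were called and the wortmannin pair varied more, so these rates need not hold there. Limma 3.58.1 and DESeq2 1.42.0 were used for alternatives, and Python 3.11.15 with scipy 1.17.1 for the remaining steps.

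The files do not pair transcript IDs with gene names. Coding lengths were therefore compared with GENCODE M21 on GRCm38, the assembly of mm10. With 9 codons subtracted from annotated lengths, 94.5% of 1466 deposited transcripts over 1500 codons had the length of some complete coding transcript. Every other shift from 0 to 20 codons matched 59.1% to 64.1%. Lengths of genes are given here with these 9 codons subtracted, on the deposited scale. A transcript took a gene's name only where its length belonged to that gene alone, which held for 584 transcripts of 424 genes. Order in the file was used only to discard names. A name stayed where at least 0.5 of the transcripts within 25 lines, of 300 codons or more, had lengths of genes within 1000000 bp. This kept 362 transcripts of 295 genes; 0.154% of randomly drawn genes passed. The share of 0.5 was set before the fold changes of named genes had been seen. A looser share of 0.3 was tried after they had been seen, and is reported only as an alternative. All kept lengths were 1111 codons or more, so the named genes are long ones.

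Fixed before the data were examined were the test, the alternatives listed first below, 28 gene lists (7 of them cell type markers) and the rule for named genes. That rule takes genes with an adjusted p under 0.05, a mean of at least 10 CPM and both wortmannin libraries on the same side of both control libraries. It names the 12 largest rises and the 12 largest falls, up to 4 members of each list with the smallest p, and a set of clock and temperature genes. Some genes that the rule took are not reported here. No list had 5 named members, so the planned limma camera test could not be run on names. Each list was instead read through stand-in transcripts, the most abundant tested transcript at the coding length of each member. Other genes share most of these lengths, so a stand-in need not be the member. This reading was devised after the most lowered transcripts had been seen to have the lengths of translation factor mRNAs. Lengths of ribosomal protein and other TOP (5' terminal oligopyrimidine) mRNAs were left out of the other lists. Camera was run on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and beside fry. Each list's median was also compared, two-sided, with 10000 random lists matched on coding length and abundance, each drawn from the 20 nearest transcripts. Transcripts were drawn independently, so these matched p-values measure the spread across transcripts and not between libraries. These p-values were adjusted by Benjamini-Hochberg over the lists that are not markers.

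Alternatives were DESeq2 size factors, library totals, no filter, at least 50 counts in 2 libraries, DESeq2, limma-voom, robust edgeR, a replicate block, each library left out, and stand-ins at ribosomal protein lengths left out. Mitochondrially encoded genes could not be left out because their transcripts were unnamed. Added after seeing the data were transcripts with distinct counts only, 1 transcript per 5 consecutive lines, libraries thinned to equal totals, the matched random lists, the looser naming share and stand-ins held fixed across fits.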

Results

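Ribosome-protected footprints were counted per transcript in warm-shifted, dexamethasone-synchronised mouse embryonic fibroblasts with and without wortmannin, an inhibitor of PI3K. The shift from 35 °C to 38.5 °C came 24 h after dexamethasone, in the rising phase of the clock gene Per2. Each group had 2 libraries. Deposited totals were 15376778 and 31110420 counts in the control libraries and 7677780 and 7485868 in the wortmannin libraries. Log2 CPM correlated at 0.993 between the control libraries, at 0.969 between the wortmannin libraries and at 0.921 to 0.943 between groups. Chi-square per degree of freedom was 1.63 for the control pair and 6.69 for the wortmannin pair, so neither pair differed by counting noise alone. Whether the libraries of a pair came from separate cells cannot be told from these values.

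The comparison asked how PI3K inhibition altered ribosome occupancy of mRNAs in warm-shifted cells. Footprints fell on 47 of 65 transcripts that stood in for ribosomal protein mRNAs by coding length and rose on 3, and footprints on many long transcripts rose by smaller amounts. The fall as a list passed against matched random lists, a test that treats transcripts as independent. The fall did not pass in camera with an estimated correlation (adjusted p = 0.793). With 2 libraries per group, that camera test gave no list an unadjusted p below 0.1135, so it could not decide. Of 26602 transcripts tested, 4215 were higher and 4596 lower with wortmannin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of all these calls, 175 rises and 208 falls were over 4-fold. Among the 23133 with distinct counts, 3584 were higher and 4125 lower. Fewer transcripts passed with either control library left out, and more with either wortmannin library left out. The spread is then taken from the other group alone. The wortmannin pair varied more (chi-square per degree of freedom 6.69 against 1.63), so these shifts need not reflect the library left out. With every library kept, DESeq2 called 2302 higher and 2691 lower.

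The transcript with the largest fall among those above 10 CPM, uc009qun.1, has 453 codons, the length of Eef1a1, the elongation factor that delivers aminoacyl-tRNA, and of 48 other genes. It went from 1651 ± 85.4 to 78.7 ± 6.70 CPM (SD, n = 2), a log2 fold change of -4.39 ± 0.13 (SE; edgeR, Benjamini-Hochberg adjusted p = 3.31e-06). Next came uc008rwn.2, of 110 codons, a length that the ribosomal protein gene Rps20 shares with other genes, at -4.20 ± 0.17. The most abundant tested transcript of that length, uc008maf.1, was at -0.20 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p = 0.428). The largest rises were uc033gah.1 at 4.26 ± 0.42, of 192 codons, the length of 102 genes if incompletely annotated isoforms are counted, among them 1 of Rpl10, whose full length is 205, and uc007mwd.1 at 3.55 ± 0.29, of 302 codons, the length of no listed TOP gene. The wortmannin libraries differed widely for the first of these, at 112 ± 72.4 CPM.

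Ribosomal proteins, the protein components of the ribosome, were read through 65 stand-in transcripts at their coding lengths. Footprints fell on 47 of them, rose on 3 and did not pass on 15. Adjusted over the list alone, 48 fell and 4 rose. The 3 rises were all among the most abundant stand-ins (uc007bkd.2 at 0.39, uc007urk.3 at 0.88 and uc009ula.2 at 1.76). The most abundant that fell, uc007upt.1, was at -0.37, and the larger falls lay in less abundant stand-ins. The ID of uc007bkd.2 is close to that of uc007bjy.2, which the looser naming share gave to Fn1 and which rose by 0.43. It may thus be of Fn1, and other abundant stand-ins need not be ribosomal protein transcripts either. The median log2 fold change of all 65 was -1.08, against -0.50 in matched random lists. Camera gave an adjusted p of 3.59e-13, but the adjusted p was 0.793 with an estimated correlation, a version that could hardly pass any list. The matched test, which treats transcripts as independent although camera estimated a correlation of 0.376, gave an adjusted p of 0.002. This came from the smallest p that 10000 lists can give. That call was lost without control replicate 1 (median -0.76, adjusted p = 0.088) and without control replicate 2 (median -0.69, adjusted p = 0.0632), where stand-ins were chosen again by abundance in the libraries left. With the same stand-ins it was kept without each of them (medians -1.06 and -1.10, 41 lower each, adjusted p = 0.002). It was also lost when these stand-ins were replaced by the next most abundant transcripts (median -0.87, adjusted p = 0.0893). Without wortmannin replicate 1 or 2 the medians were -2.07 and -1.82 with stand-ins chosen again, and -1.34 and -0.91 with stand-ins held fixed. With 1 transcript per 5 consecutive lines the median was -2.06 (50 lower), and -2.03 over the 48 of these stand-ins that remained (38 lower), with the call kept. The stand-ins are not all independent: uc007srd.1 and uc007sre.1 had nearly equal CPM in every library, as had uc007lfj.2 and uc007lfk.2. Stand-ins ranged from -3.59 to 1.76, and transcripts of other genes with the same lengths can be among them.

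Among 3636 transcripts of at most 410 codons and at least 10 CPM, 598 had a ribosomal protein length, or 16.4%. Of the 100 most lowered, 75 had one (two-sided Fisher's exact test, p = 1.3e-39, across transcripts, which are not independent replicates). Of the 100 most raised, 18 had one (the same exact test, p = 0.681). At other cut-offs, 34 of the 50 and 103 of the 200 most lowered had one (68% and 51.5%). Among the most raised these were 8 of 50 and 29 of 200. This test was chosen after the most lowered transcripts had been seen.

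Other TOP mRNAs carry the same 5' motif as ribosomal protein mRNAs and encode elongation and initiation factors as well as other proteins, such as vimentin (Vim) and Npm1. They gave 19 stand-ins. Of these 17 fell, 1 rose and 1 did not pass; adjusted over the list alone, 17 fell and 2 rose. The median log2 fold change was -1.26, against -0.20 in matched lists (adjusted p = 0.002). Without control replicate 1, 10 fell (median -0.93), and without control replicate 2, 9 fell (median -0.71), with stand-ins chosen again. With the same stand-ins 11 and 10 fell (medians -1.33 and -1.20), and the call was kept in each case. Camera gave 1.91e-07, with an adjusted p of 0.793 with an estimated correlation, which was 0.227. Their share of counts went from 0.829% ± 0.0297 to 0.265% ± 0.0161 (SD, n = 2). The most abundant, at the length of Vim, went from 1842 and 1968 to 442 and 337 CPM. The share of the ribosomal protein stand-ins went from 1.47% ± 0.0253 to 1.11% ± 0.0317. The most abundant of these stand-ins weigh most in this share and need not be ribosomal protein transcripts.

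**Figure D1:**
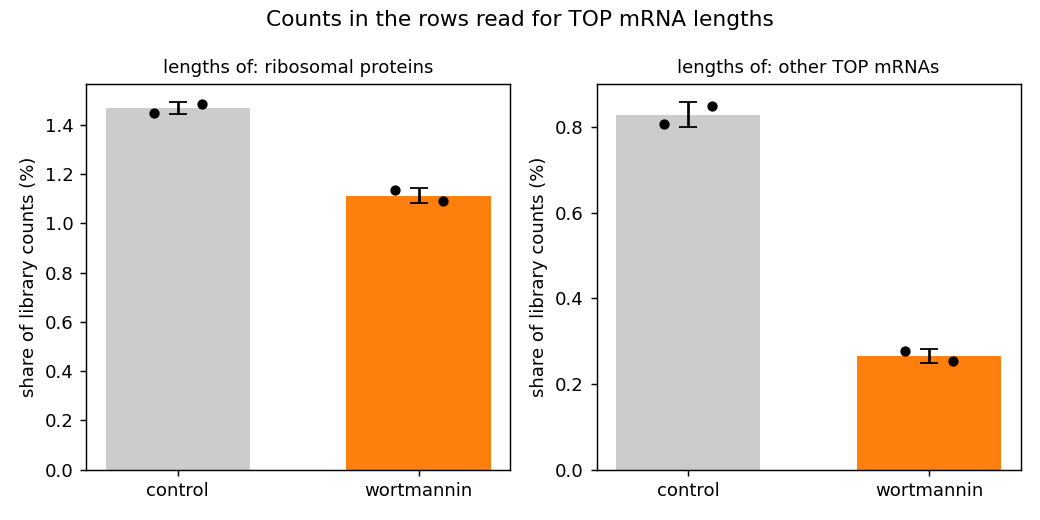
Share of each library's counts (%, transcripts with distinct counts) in the stand-in transcripts at ribosomal protein lengths (left) and at other TOP mRNA lengths (right). Bars are means of 2 libraries, error bars SD and points single libraries; the other TOP share went from 0.829% to 0.265%.

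The fold change rose with coding length. Median log2 fold change was -0.40 for 733 transcripts under 100 codons, 0.05 for 7826 of 400 to 800 codons and 0.56 for 75 of 3200 codons or more, of which 58.7% rose and 1.33% fell. Spearman's rho across 23133 transcripts with distinct counts was 0.233, and transcripts are not independent replicates.

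**Figure D2:**
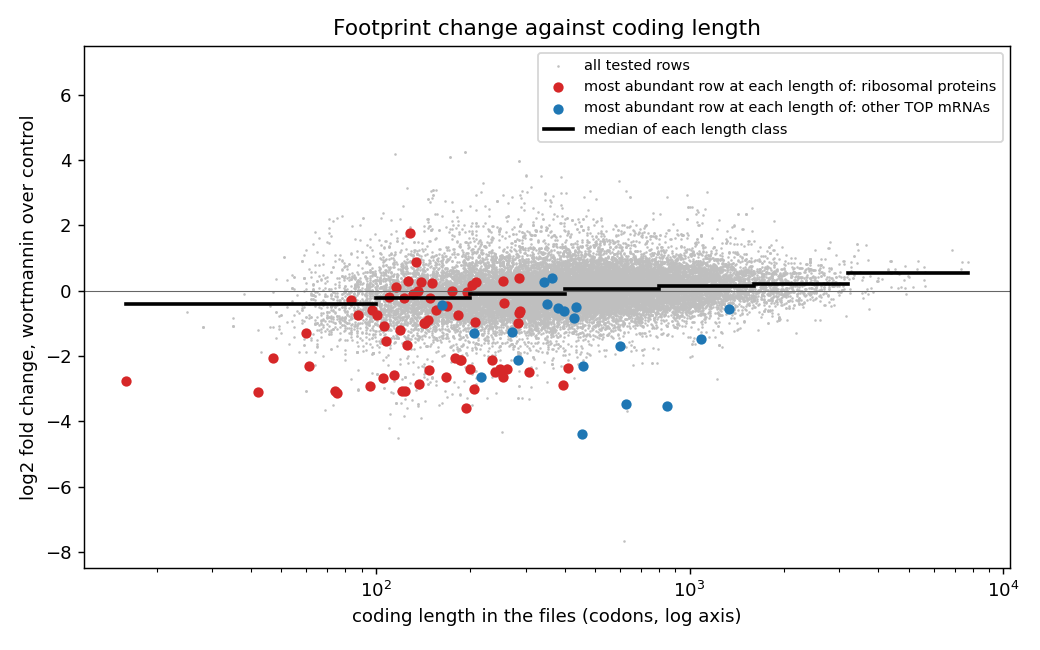
Log2 fold change (wortmannin over control) against coding length in codons on a log axis; grey points are tested transcripts, coloured points the stand-ins at TOP mRNA lengths, and black lines the medians of length classes. Class medians run from -0.40 to 0.56, and most coloured points lie below 0.

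Among the other lists, oxidative phosphorylation (nuclear-encoded respiratory chain subunits) had 22 of 38 stand-ins lower and 4 higher. Camera gave an adjusted p of 0.00122, and the adjusted p was 0.793 with an estimated correlation. Its median of -0.39 was close to the -0.36 of matched lists (adjusted p = 0.928). Mitochondrially encoded subunits gave 11 stand-ins, 4 higher, 3 lower and 4 not past the threshold. Their median was 0.27, against -0.27 in matched lists (adjusted p = 0.0133), while camera gave 0.794. Without wortmannin replicate 1 the median was 0.0086 and the adjusted p 0.191. With 1 transcript per 5 consecutive lines the median turned to -0.033 (adjusted p = 0.329).

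No other list passed camera or the matched test after Benjamini-Hochberg adjustment. No camera call held with an estimated correlation, which could hardly pass any list with 2 libraries per group. Fry, which does not compare a list with other genes, also passed circadian clock (adjusted p = 0.0343) and heat shock (adjusted p = 0.0314), both downward. Heat shock chaperones had 9 of 21 stand-ins lower and 3 higher (camera adjusted p = 0.0847). Circadian clock genes had 9 of 20 lower and 5 higher, FOXO targets 10 of 24 lower and 5 higher, and ATF4 targets 12 of 29 lower and 6 higher. PI3K-AKT-mTOR components had 10 of 28 higher and 6 lower; camera's direction was up and fry's down. The list passed the matched test without wortmannin replicate 1 (median 0.24, adjusted p = 0.044). Genes regulated by upstream open reading frames had 7 of 18 higher and 5 lower, with a median of -0.09 and an upward camera direction. Endoplasmic reticulum chaperones had 9 of 20 lower and 5 higher, and sterol and fatty acid synthesis 9 of 30 lower and 6 higher. Immediate early genes had 11 of 30 lower and 7 higher, and glycolysis 6 of 17 in each direction; without wortmannin replicate 2 glycolysis passed the matched test (median -0.69, adjusted p = 0.019). Cell cycle genes had 7 of 29 lower and 6 higher, with a median of 0.07 and a downward camera direction. Matrix and contractile genes had 12 of 31 lower and 10 higher, and glucocorticoid targets 5 of 15 in each direction. Autophagy and lysosome genes had 10 of 30 lower and 7 higher, ribosome biogenesis 9 of 29 lower and 5 higher, and histones 2 of 7 in each direction. Cold-inducible RNA-binding genes had 3 stand-ins, 2 of them lower.

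Marker lists were read in the same way, with unadjusted p-values. Fibroblast markers had 6 of 9 stand-ins lower and 3 higher (median -0.76, permutation p = 0.0154 from matched lists), while camera gave 0.141, and 0.427 with an estimated correlation. Macrophage markers had 4 of 8 lower, endothelial 2 of 9 lower and 3 higher, epithelial 4 of 8 lower and 1 higher, and muscle 5 of 10 lower and 1 higher. Neural markers had 6 of 9 lower and adipocyte markers 4 of 8 lower. For these 6 lists the p from matched lists was 0.28 or more. Camera gave 0.0128 for neural and 0.021 for macrophage markers, and 0.123 and 0.214 with an estimated correlation.

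Per2, a repressor of the circadian clock, has a coding length of 1248 codons on the deposited scale, 9 below the annotated length. Inppl1, Ppfia2, Prdm16 and Synpo2 share it. Among transcripts of that length, 3 with distinct counts were tested. None fell, and 1 rose, from 18.2 ± 1.28 to 26.9 ± 3.14 CPM (SD, n = 2; log2 fold change 0.57 ± 0.13, edgeR Benjamini-Hochberg adjusted p = 0.0104). This rise did not pass without control replicate 1 (0.63, adjusted p = 0.081) or control replicate 2 (0.49, adjusted p = 0.198). The other values were 0.20 ± 0.17 and 0.00 ± 0.35. Which of them is Per2 was not determined, so the transcript that rose may belong to another gene of this length. At the length of Per1, 1282 codons, shared with 4 other genes, 5 transcripts with distinct counts were tested. Of these 3 rose and none fell, with log2 fold changes from 0.24 to 0.96. Cry1, Cry2, Arntl, Clock, Nr1d1, Dbp, Hspa1a, Hspa1b, Cirbp and Rbm3 have lengths shared by 11 to 45 tested transcripts each, and no value is given for them.

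A name could be given to 213 tested genes, all long, of which 73 rose, 11 fell and 129 did not pass (edgeR, Benjamini-Hochberg). Of all transcripts of 1600 to 3200 codons, 28.3% rose and 6.84% fell. Without control replicate 1 the named counts were 32 and 4, and without control replicate 2 they were 21 and 4. Without wortmannin replicate 1, 24 fell, and without wortmannin replicate 2, 22 fell.

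The histone demethylase Kdm5a rose by 1.35 ± 0.11 on the log2 scale (chromosome 6, 120364124 to 120444574, GRCm38), from 31.5 ± 0.82 to 79.9 ± 4.99 CPM. Zfyve26 rose by 1.24 ± 0.13 and Helz2 by 1.10 ± 0.18. Other rises taken by the naming rule were the kinase Cdk12 (1.04 ± 0.12), the Mediator subunit Med13 (0.995 ± 0.13), Asxl1 (0.95 ± 0.11), the osmotic stress factor Nfat5 (0.93 ± 0.11) and Srcap (0.88 ± 0.12). Wdr81 (0.99 ± 0.12), the cytoskeletal linker Dst (0.89 ± 0.14) and the cholesterol exporter Abca1 (0.85 ± 0.12) also rose. Adjusted p-values of these 11 genes lay between 5.66e-05 and 0.00225 (edgeR, Benjamini-Hochberg).

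Falls among named genes were smaller. Atrn (chromosome 2, 130906495 to 131030333) fell most, from 41.1 ± 0.328 to 20.8 ± 0.534 CPM (log2 fold change -0.98 ± 0.11), followed by the splicing cofactor Srrm2 at -0.91 ± 0.12. Tsc2, a subunit of the complex that restrains mTORC1 (chromosome 17, 24595816 to 24632630), was at -0.61 ± 0.11. Further falls were Vps13a (-0.76 ± 0.12), the basement membrane protein Nid1 (-0.64 ± 0.10), the lipid kinase Pi4ka (-0.52 ± 0.13), Apc (-0.48 ± 0.12), the nuclear pore protein Nup214 (-0.46 ± 0.11) and Ltbp4 (-0.44 ± 0.13). Without control replicate 1 or 2, Tsc2 (-0.58 and -0.65, adjusted p = 0.0859 and 0.0644) and Nid1 (-0.63 and -0.65, adjusted p = 0.0599 and 0.058) no longer passed. Nor did Pi4ka (-0.48 and -0.58), Apc (-0.47 and -0.50), Nup214 (-0.45 and -0.47) and Ltbp4 (-0.41 and -0.48), with adjusted p from 0.111 to 0.258; these 4 did not pass in DESeq2 either. A transcript with the length of Myh4 was at -0.84 ± 0.11, an uncertain name because myosin heavy chain genes lie in tandem with nearly equal lengths.

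**Figure D3:**
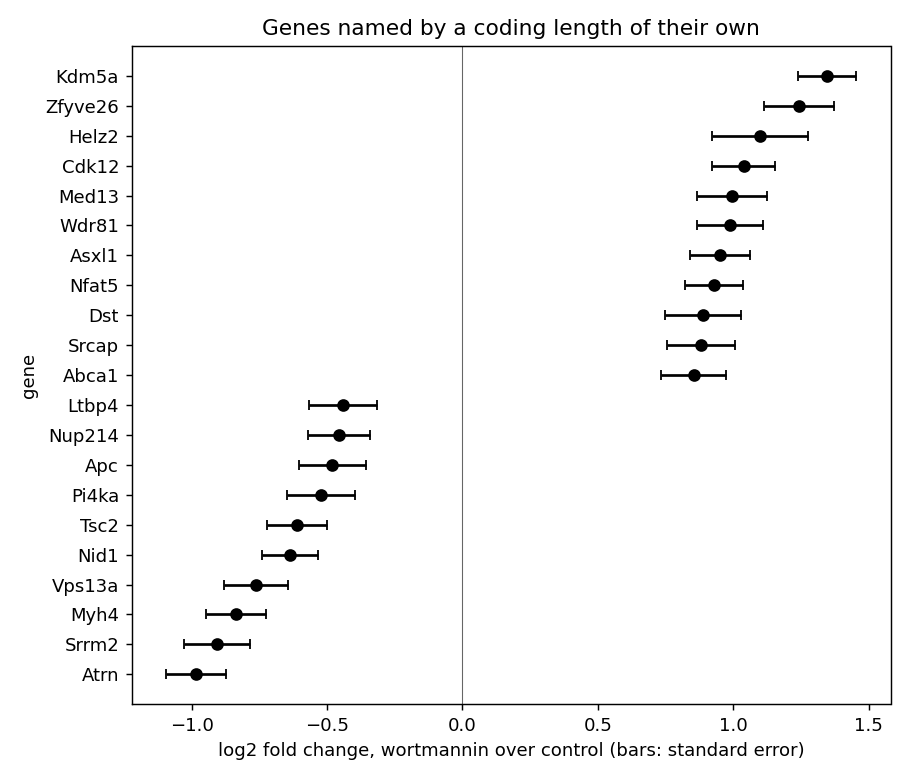
Log2 fold change (wortmannin over control) of 21 genes that the naming rule took, with standard errors as bars. The 11 rises run from 0.85 to 1.35 and the 10 falls from -0.98 to -0.44.

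Named list members were few. Mtor was at 0.21 ± 0.12 (adjusted p = 0.208), Fasn at -0.07 ± 0.13, Acaca at 0.06 ± 0.15, Cad at -0.06 ± 0.16, the collagen Col5a1 at -0.08 ± 0.14 and the neural marker Nes at 0.07 ± 0.17, none past the threshold. Without wortmannin replicate 1, Mtor (0.30, adjusted p = 0.0171), Acaca (0.27) and Col5a1 (-0.30) passed, and without wortmannin replicate 2, Fasn (-0.26) and Cad (-0.34) passed. Of the matrix genes, Col6a3 rose by 0.73 ± 0.17 (adjusted p = 0.0118) and Fbn1, the main protein of microfibrils, by 0.33 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 0.0351). Without control replicate 1 or 2 neither passed: Col6a3 was at 0.77 and 0.69 (adjusted p = 0.0719 and 0.118) and Fbn1 at 0.33 in both (adjusted p = 0.373 and 0.407). Nor did Fbn1 pass in DESeq2 (adjusted p = 0.0918), with a replicate block (0.0858), without a low-count filter (0.0608) or with library totals only (0.0514).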

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

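Tests with distinct transcripts, 1 transcript per 5 lines, thinning, the looser naming share and fixed stand-ins were chosen after seeing the data. DESeq2 called 2302 transcripts higher and 2691 lower, and 1 transcript per 5 lines, with fewer tested, 1641 and 1820. With 1 library left out, counts ran from 1269 to 5724 higher and from 1853 to 6283 lower; the lone library of a group is then assumed to vary like the other group. Named genes ran from 21 to 101 higher and from 4 to 24 lower, and DESeq2 gave 7 lower. The looser naming share of 0.3 named 254 genes, 87 higher and 12 lower; 17 of the reported genes taken by the rule were the same, Abca1, Dst, Nfat5 and Srcap were replaced, and Chd6, Piezo2, Smg1, Vps13c and Zfhx3 entered. The replicate numbers are only shared: deviations of same-numbered libraries correlated at -0.147, and with a replicate block 3729 transcripts were higher and 4134 lower. Medians at ribosomal protein lengths ran from -2.07 to -0.69 with a library left out, with the call lost without either control library. With stand-ins held fixed they were -1.06 and -1.10 there, and -1.34 and -0.91 without wortmannin replicates 1 and 2, all with the call kept. With the ribosomal protein stand-ins left out, the next most abundant transcripts gave -0.87 and the call was lost. With 1 transcript per 5 lines the ribosomal protein median was -2.06, or -2.03 with the 48 stand-ins that remained, with the call kept. For other TOP lengths the medians ran from -1.51 to -0.71, and with stand-ins held fixed from -1.40 to -1.05. Mitochondrially encoded lengths ran from 0.0086 to 0.36, the call being lost without wortmannin replicate 1, and reversed to -0.033 with 1 transcript per 5 lines. In camera with an estimated correlation the adjusted p was 0.793 for ribosomal proteins, 0.793 for other TOP mRNAs and 0.793 for oxidative phosphorylation. No list had an unadjusted p below 0.1135 in that camera test, so these values decide little. Spearman coefficients with coding length were 0.211 without a filter, 0.32 with at least 50 counts in 2 libraries, 0.315 with 1 transcript per 5 lines, and 0.182 to 0.233 with a library left out. Where no cause is given it was not tested. No transcript of Per2's length fell under any alternative. Of 460 values of 29 named genes under alternatives, 431 counted as unchanged, 24 no longer passed and 5 newly passed in the same direction. Among genes that passed in the main test, 0 values reversed. For the other genes a change of direction was counted as unchanged, so reversals among them were not counted. By this count 16 genes were unchanged throughout, and several lost their call without either control library. At the deposited depths 15.2% of simulated 1.5-fold changes were called, in a simulation with few changes and equal spread in both groups. Thinning to equal totals left 3229 transcripts higher and 3725 lower.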

Other observations

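Values at 3 further lengths were chosen after they had been seen. At 1312 codons, the length of Irs2, an adaptor of the insulin receptor, and of Abcb11 and Mast3, 1 of 2 tested transcripts rose from 58.9 ± 2.26 to 211 ± 20.3 CPM (SD, n = 2; log2 fold change 1.84 ± 0.11). The other was at -0.29 ± 0.11, which did not pass. At 1444 codons, the length of the collagen Col1a1 and 3 other genes, the most abundant of 3 tested transcripts fell from 20096 ± 36.4 to 11901 ± 1819 CPM (log2 fold change -0.76 ± 0.14). Of the others, 1 rose by 0.41 ± 0.12 and 1 was at -0.23 ± 0.14, which did not pass. At 2468 codons, shared by the matrix protein Fn1 with Son and Sptan1, both tested transcripts rose, by 0.44 ± 0.12 and 0.63 ± 0.10. Which gene each transcript belongs to was not determined.

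The 3 patterns weighed here were noticed in these data, and the predictions were written before the tests were run; thinning, the matched lists and 1 transcript per 5 consecutive lines were chosen after seeing the data.

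Stand-ins at ribosomal protein lengths were lower with wortmannin. Lower depth of the wortmannin libraries was predicted to bring the median towards 0 after thinning, and it was -0.996, against -1.08 before. Thinning keeps each transcript's expected share of a library, so it could hardly move this median and does not decide on depth. Under the other normalizations the higher median was -1.07. Short coding length alone is argued against by 0 of 10000 matched lists (0%) with a median as low in all 4 libraries. The lists treat transcripts as independent, so this share does not measure the spread between libraries. With stand-ins chosen again the share was 1.31% without control replicate 1, not under the 1% set beforehand, and 0.78% without control replicate 2. With the same stand-ins it was 0% without any 1 library. An effect of the inhibitor stays open, and whether it lies in translation or in mRNA level was not tested, since mRNA libraries were not analysed here.

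Fold change rose with coding length. TOP lengths alone do not account for it, since rho was 0.221 without all transcripts at those lengths. After thinning rho was 0.241, but thinning keeps each transcript's expected share, so this decides little on depth. With 1 transcript per 5 consecutive lines rho was 0.315, which argues against repeated isoforms. A difference in the size of footprints recovered or in ribosome run-off during lysis may also act along length and was not tested.

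Wortmannin libraries differed more from each other than control libraries did, with an SD of log2 ratios of 0.337 against 0.116. After thinning, the control value divided by the wortmannin value was 0.511, below the 0.8 that depth alone would need. Separate experiments with different inhibitor exposure may contribute, which the labels do not allow to be tested.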
